A study of Arabidopsis thaliana with 24 samples.

How the data were processed

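Whole Arabidopsis thaliana seedlings of 3 genotypes were profiled by RNA sequencing. The genotypes were an aequorin-expressing Col-0 line, called WT here, and the mutants card1-1 and card1-2 made in that line. Aequorin is a calcium-reporting photoprotein. Seedlings grown in liquid medium for 7 days received 5 µM DMBQ (2,6-dimethoxy-1,4-benzoquinone), or the same volume of the solvent DMSO as a mock treatment, for 10 min. The 6 groups held 4 libraries each, 24 in all, and groups and replicate numbers were taken from the sample labels. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, part of which may be technical.

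RNA extraction and library preparation followed the published method of Townsley and co-workers, per the labels' protocols, and sequencing was done on an Illumina HiSeq4000, per the series description. CASAVA, bcl2fastq 2.17, TopHat2 2.1.1, TopHat, HTSeq 0.6.1 and the genome build TAIR10 are named, without role or order, per the submitters' processing notes. The annotation release, the strand setting and the overlap mode of the counting are not given in the sources used here. Reads from overlapping or antisense genes therefore cannot be told apart. The table deposited by the authors gives a whole-number read count per gene and library, not normalized. Its numeric columns also carry 1 line of fractions, so their unit was recorded in the class of estimated counts, although every deposited gene value is a whole raw count and nothing was rounded. The 9 lines that name no gene were left out of library sizes and tests. They hold the HTSeq tallies, among them the alignments that were not unique, which tally alignment records and not reads. The share not unique ran from 17.3% to 66.5% of all counted records, that without a feature from 1.86% to 3.10% and that of ambiguous records from 0.149% to 0.360%.

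Of 33602 genes, 32835 matched a gene of the reference annotation (assembly TAIR10.1) by AGI code, and names, exonic length and GC content were taken from it. Coordinates are those of that assembly. Gene counts per library ran from 2048246 to 9000207. Across the 36 pairs of replicates within groups, the chi-square of the counts divided by its degrees of freedom lay between 3.78 and 29.2 over genes with at least 10 counts in the pair, so no pair matched within sampling noise and all libraries were kept as separate replicates.

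Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 17734 genes. Library sizes were scaled by TMM. The main test was edgeR 4.0.16's quasi-likelihood test with robust estimation in R 4.3.3, fitted to all 24 libraries with a term for each of the 6 groups and no block. It was two-sided, with Benjamini-Hochberg adjustment within each of 8 comparisons and a threshold of 0.05. The comparisons were DMBQ against mock in each genotype, the difference of that response between each mutant and WT and between the mean of both mutants and WT, and each mutant against WT without DMBQ. Every adjusted p given for a single gene comes from this test unless another fit is named beside it, and log2 fold changes are given with the standard error (SE) of that fit. Normalised read counts are TMM-scaled CPM, with the library total set to 1e6, given as mean ± SD.

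Genes raised by DMBQ in WT were followed in the mutants as a set, by the median of their log2 fold changes and by fry (limma 3.58.1) on voom values. Its p-values were adjusted by Benjamini-Hochberg over both mutants, and for levels over both mutants and treatments, a step added after the results were seen. They were also chosen on WT replicates 1 and 2 and measured on replicates 3 and 4, and this was repeated with the share of alignments not unique as a covariate. The design fixed 18 gene lists with 287 members before the data were examined. They cover calcium and touch, WRKY factors, ERF and DREB factors, zinc finger factors, jasmonate, reactive oxygen, electrophile detoxification, pattern-triggered immunity, ethylene synthesis, heat shock, auxin, abscisic acid, salicylic acid, the circadian clock, photosynthesis as a shoot marker, roots, seed storage as an embryo marker, and the CARD1 receptor kinase clade. Lists were tested with limma's camera with a preset correlation of 0.01 on voom values, adjusted over the lists within a comparison. Each list test was repeated with the correlation between its genes estimated from the data. Members past the threshold were counted over all genes and adjusted over the list alone.

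Genes to be named were fixed by rule before the data were examined. The rule took CARD1 first. For the WT response it took the 15 genes that rose and the 10 that fell most among those past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries. Where fewer than 5 passed in a direction, the 5 with the smallest p were taken whatever their level. It took 5 genes per direction in each mutant, the 8 smallest p per direction for the difference of both alleles from WT, and for the mutants without DMBQ the 8 per direction past the threshold in both alleles and the 3 per direction past it in 1 allele with an unadjusted p above 0.05 in the other. It also took up to 4 members of each list by smallest p. Genes outside this rule are said to have been chosen after their values were seen.

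The pipeline was tested on simulated counts drawn from the means and sizes of these libraries with 200 changed genes. For the WT response, over 17472 simulated genes, edgeR recovered 35% of the 2-fold and 85% of the 4-fold changes, with 7 false calls among 127. For the difference of both alleles from WT it recovered 15% of the 2-fold and 75% of the 4-fold changes. A simulation with each group's own spread held 17415 genes. Library measures were compared by exact two-sided permutation tests, whose smallest possible p with 4 libraries against 4 is 0.0286, adjusted over 42 tests. An adjusted p under 0.05 would need most of these tests to reach that value. Correlations of library measures used exact permutation as well. A library was set apart from the other 3 of its group where its gap to the nearest, divided by the range, exceeded Dixon's 95% critical value. For comparisons that share the WT mock libraries, all mock groups, WT included, were simulated 100 times as unchanged.

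Alternatives fixed before the data were examined were size factors of the RLE kind, total counts alone, no filter, a stricter filter (at least 1 CPM in at least 8 libraries), DESeq2 1.42.0, limma voom with sample quality weights, fits on the groups compared alone, the replicate number as a block, a log2 fold change of at least 1, an adjusted p under 0.01, and each library left out in turn. Chosen after seeing the data were leaving out the 3 libraries with over 55% of alignments not unique (card1-1 DMBQ replicates 1 and 4, card1-2 DMBQ replicate 3), that share as a covariate, thinning all libraries to 2048246 counts, leaving out organelle and ribosomal RNA genes, and offsets for GC content and exonic length. Data preparation and figures used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.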

Results

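Transcript levels were measured by RNA sequencing in whole 7-day-old seedlings of WT and of the mutants card1-1 and card1-2, each given 5 µM DMBQ or DMSO for 10 min (4 libraries per group, 24 in all). DMBQ is a quinone that parasitic plants sense as a host signal. CARD1 (AT5G49760, also known as HPCA1) encodes a leucine-rich repeat receptor kinase known to act in the perception of quinones and hydrogen peroxide. The comparisons ask which transcripts respond to DMBQ within minutes, how far that response differs in the card1 mutants, and whether the mutants differ from WT without DMBQ. Mean gene counts per library were 5008559 in WT mock, 3246532 in WT DMBQ, 3593486 in card1-1 mock, 2490986 in card1-1 DMBQ, 2827371 in card1-2 mock and 4246574 in card1-2 DMBQ, and single libraries held 2048246 to 9000207 counts.

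CARD1 lies on chromosome 5 from 20216332 to 20221382 on the plus strand, in 19 exons (TAIR10.1). Its normalised read count was 71.4 ± 5.41 CPM (SD, n = 4) in WT mock, 54.1 ± 6.03 in card1-1 mock and 52.8 ± 12.7 in card1-2 mock. With DMBQ it was 83.3 ± 7.67 CPM in WT, 65.7 ± 18.1 in card1-1 and 66.6 ± 18 in card1-2. No difference passed the test: the log2 difference from WT without DMBQ was −0.40 in card1-1 and −0.44 in card1-2 (adjusted p = 1 for both). The sources used here do not describe the lesions, and a change in coding sequence need not alter the transcript level, so these values do not check the genotype labels.

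The libraries differed in quality between groups. The share of alignments that were not unique was 24.7% ± 3.99 (SD, n = 4) in WT mock, 25% ± 6.16 in card1-1 mock and 37.3% ± 3.18 in card1-2 mock. With DMBQ it was 33.4% ± 5.65 in WT, 55.9% ± 8.06 in card1-1 and 47.8% ± 12.1 in card1-2. DMBQ against mock gave exact permutation p = 0.0286 in WT and in card1-1, the smallest value this design allows, and 0.143 in card1-2; after adjustment over 42 tests these were 0.120, 0.120 and 0.240. At equal depth, 18303 genes were detected on average in card1-1 DMBQ and 18831 in card1-2 DMBQ, against 19577 to 19737 in the other 4 groups. Fitted group by group, the biological coefficient of variation was 45.9% in card1-1 DMBQ and 41.4% in card1-2 DMBQ, and 19.3% to 28.0% in the other groups.

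**Figure D1:**
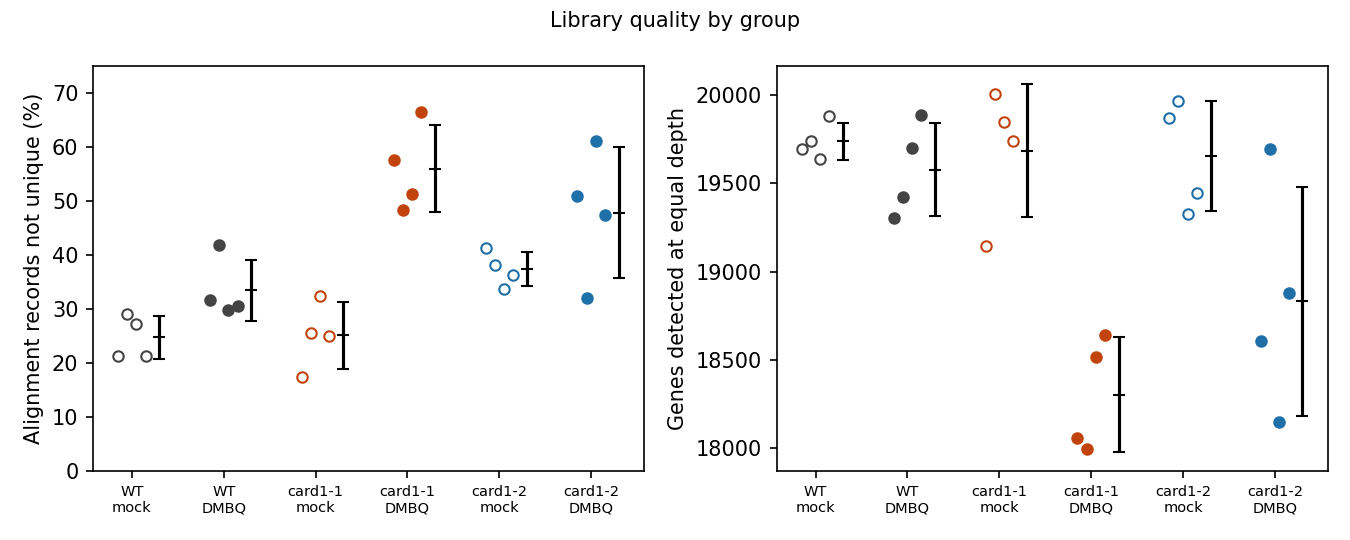
Share of alignment records that were not unique, in percent (left), and number of genes detected after thinning all libraries to equal depth (right), by group. Points are libraries and bars are the mean ± SD (n = 4); the right axis does not start at 0, and card1-1 DMBQ has the highest mean share (55.9%) and the lowest mean number of genes (18303).

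In WT, 10 min of DMBQ raised genes of early stress and immune signalling. ZAT10, a zinc finger repressor of stress responses, rose from 1.21 ± 1.03 to 30.4 ± 7.11 CPM (SD, n = 4; log2 fold change 4.45, SE 0.57, edgeR adjusted p = 1.87e-06). ERF5, an ethylene response factor active in defence, rose from 10.5 ± 0.671 to 97.1 ± 19.1 CPM (3.21, SE 0.26, adjusted p = 2.88e-11). CAF1a, a subunit of the deadenylase that shortens mRNA tails, rose from 19.2 ± 2.55 to 202 ± 27.1 CPM, and DIC2, a mitochondrial dicarboxylate carrier, from 32.2 ± 5.29 to 380 ± 41.6 CPM. In all, 180 genes rose and 2 fell at an adjusted p under 0.05 by edgeR's quasi-likelihood test, 162 of them by at least 2-fold.

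The genes with the largest increases by the naming rule included AT3G29000 (log2 fold change 6.03), AT3G02840 (5.91), WRKY46 (4.32), AT3G10930 (3.79), AT4G29780 (3.77), AT1G66090 (3.67), WRKY40 (3.58), MYB15 (3.33), ERF105 (3.26), ERF104 (3.25) and ZAT12 (3.25). MYB15 lost its call without WT DMBQ replicate 1 (adjusted p = 0.0507, and at most that over all 23 alternatives). The genes that fell were AT4G26600, from 49.6 ± 3.16 to 25.8 ± 5.96 CPM (log2 fold change −0.94, adjusted p = 0.0347), and the beta-tubulin gene TUB3, from 323 ± 47.6 to 225 ± 7.60 CPM (−0.52, adjusted p = 0.0474). AT4G26600 lost its call in 10 of 23 alternatives and TUB3 in 15 of 23; in both genes 7 of these left out 1 WT library. TUB3 and TUB2 are near-identical copies. Reads that align to both can be tallied as not unique and left out of both counts, and the share not unique differed between groups, so their values are uncertain. PRK, the Calvin cycle phosphoribulokinase, had a log2 fold change of −0.50 that did not pass (adjusted p = 0.0523).

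Transcription factor lists moved together in WT. Of 11 measured ERF and DREB factors 8 rose, or 10 adjusted over the list alone, with a median log2 fold change of 3.21 (camera adjusted p = 4.3e-32). Of 10 zinc finger factors 5 rose, or 8 adjusted over the list alone (median 2.88, camera adjusted p = 4.6e-22), with SZF1 at 2.80 and CZF1 at 2.25. Of 15 WRKY factors 6 rose, or 10 adjusted over the list alone (median 0.97, camera adjusted p = 1.1e-23). WRKY33, a regulator of camalexin defence, rose from 77.7 ± 6.04 to 444 ± 42.4 CPM, and WRKY18 rose from 34.2 ± 6.16 to 125 ± 19.1 CPM. No member of these 3 lists fell. Their calls held with an estimated correlation (adjusted p = 2.1e-05, 3.3e-05 and 1.2e-05).

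Calcium and immunity genes rose as well. Of 16 calcium and touch genes 6 rose, or 11 adjusted over the list alone, and all 16 lay above 0 (median 1.48, camera adjusted p = 2.8e-26). CML24, a calmodulin-like protein also known as TCH2, rose from 87.2 ± 9.12 to 280 ± 24.6 CPM, and the calcium-dependent kinases CPK28 and CPK32 rose by log2 fold changes of 1.54 and 1.34. Of 20 pattern-triggered immunity genes 7 rose, or 13 adjusted over the list alone (median 1.22, camera adjusted p = 2.8e-26). The ubiquitin ligase genes PUB22 and PUB23, known to damp immune signalling, rose by 2.18 and 2.98, and the syntaxins SYP121 and SYP122 by 1.18 and 1.60. Of 6 ethylene synthesis genes 3 rose, or 5 adjusted over the list alone (median 1.06, camera adjusted p = 2.8e-11): ACS6 (2.44), ACS7 (1.62) and ACS11 (2.35), all encoding ACC synthases. ACS11 lost its call in 6 of 23 alternatives, 5 of which left out 1 WT library. These 3 lists kept their calls with an estimated correlation (adjusted p = 4.0e-05, 1.2e-05 and 4.0e-05).

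Of 17 jasmonate genes 2 rose, or 3 adjusted over the list alone: JAZ1, a jasmonate repressor, by 2.27 and MYC2, its target transcription factor, by 1.25 (list median 0.66, camera adjusted p = 3.5e-06, but adjusted p = 0.0767 with an estimated correlation). No abscisic acid gene of 9 and no salicylic acid gene of 7 passed over all genes, and 1 of each passed adjusted over the list alone. Their medians of 0.37 and 0.39 gave camera adjusted p = 0.00035 and 0.0035 (adjusted p = 0.0445 and 0.0320 with an estimated correlation). No member of 23 detoxification genes passed, by either count, with a median of 0.28 (camera adjusted p = 0.0080; adjusted p = 0.447 with an estimated correlation). Photosynthesis genes had a median of 0.15 with none of 17 past the test (camera adjusted p = 0.0173; adjusted p = 0.517 with an estimated correlation).

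The remaining lists were not called in WT by camera. Reactive oxygen enzymes had a median of −0.08 (adjusted p = 0.767), auxin genes −0.08 (0.738), clock genes −0.01 (0.738), root markers 0.09 (0.399) and the CARD1 clade 0.09 (0.985). Heat shock genes had a median of −0.23 and a mean of −0.05 while the test pointed up (adjusted p = 0.738), and 1 of 19 rose, the heat shock factor HSFB2A (1.89, adjusted p = 0.0347, a call lost in 9 of 23 alternatives). Of 12 seed storage genes none was expressed enough to be tested. The number of genes called in WT was 349 (316 higher, 33 lower) when WT was fitted alone, 372 (348 and 24) with limma voom and 117 (116 and 1) without WT mock replicate 2.

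**Figure D2:**
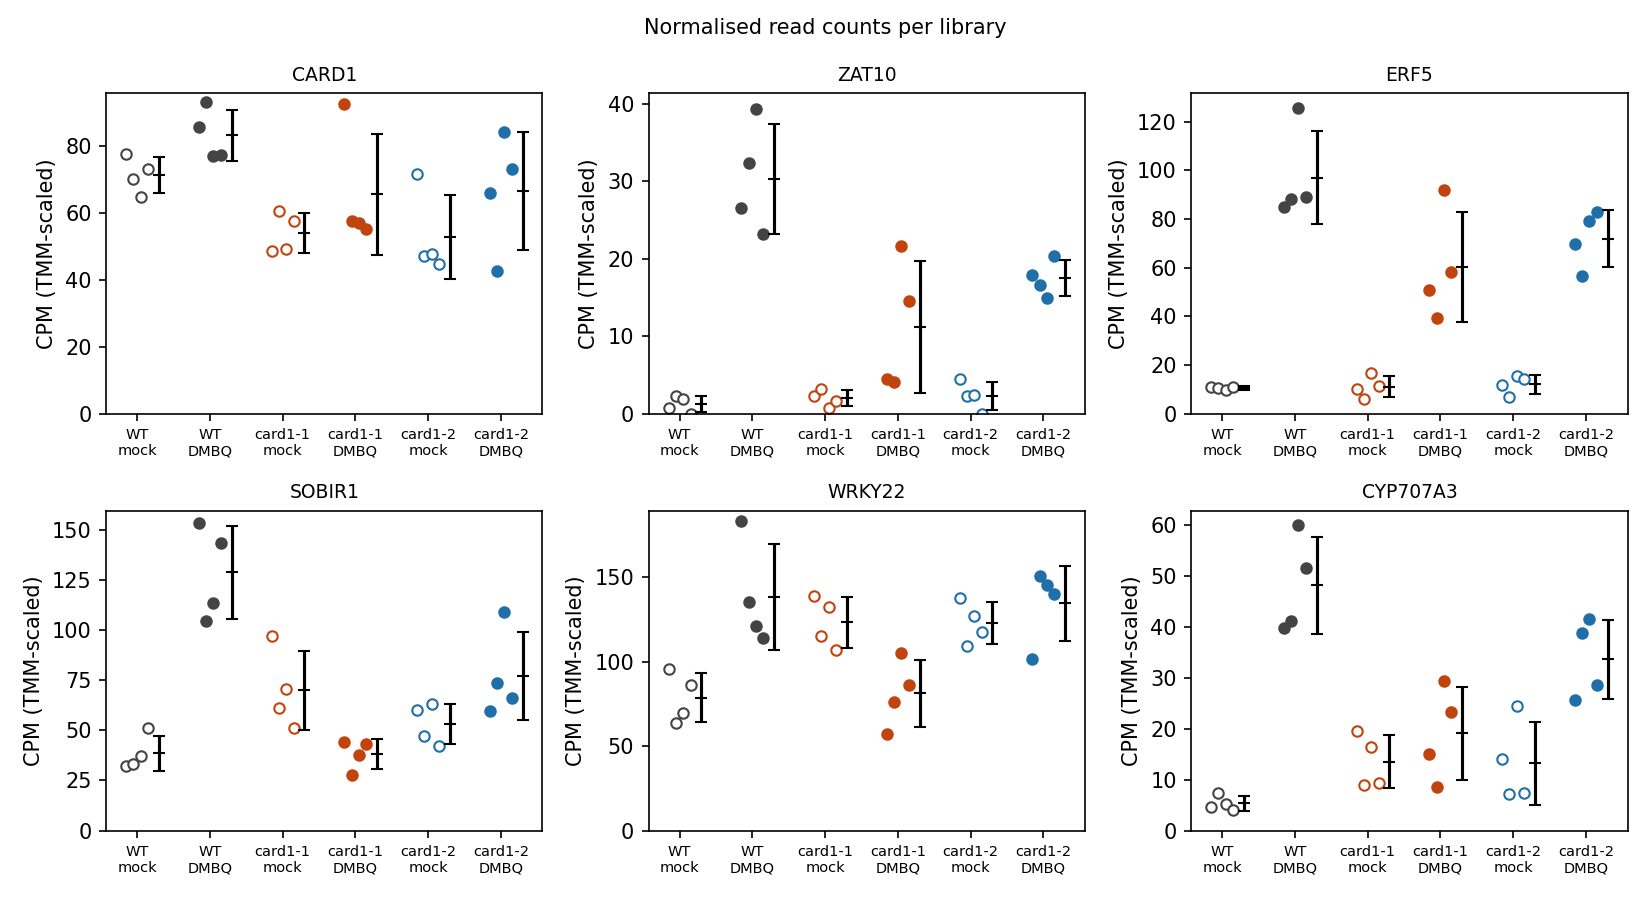
Normalised read counts (TMM-scaled CPM) of CARD1, ZAT10, ERF5, SOBIR1, WRKY22 and CYP707A3 in each library, by genotype and treatment. Points are libraries and bars are the mean ± SD (n = 4); SOBIR1 went from 38.5 to 129 CPM in WT and from 70 to 38.3 CPM in card1-1.

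In card1-1, DMBQ raised many of the same genes by less and was accompanied by a broad set of other differences. ERF5 rose from 11.1 ± 4.37 to 60.2 ± 22.7 CPM (SD, n = 4; log2 fold change 2.46, SE 0.27, edgeR adjusted p = 1.03e-07) and CAF1a from 15 ± 3.12 to 104 ± 45.8 CPM (2.80, SE 0.27, adjusted p = 1.03e-07). ZAT10 rose by 2.44 and WRKY40 by 2.21. PBP1 (AT5G54490), which encodes a calcium-binding partner of the PINOID kinase, rose by 3.01. The receptor-like kinase gene SOBIR1 fell, from 70 ± 19.8 to 38.3 ± 7.5 CPM (−0.87, SE 0.22, adjusted p = 0.0097).

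A total of 629 genes rose and 560 fell in card1-1 at an adjusted p under 0.05 by edgeR, 411 of them by at least 2-fold. The rule's other genes that rose were the plastid genes ATCG00140 (3.8; 31.3 ± 22.0 to 429 ± 58.6 CPM) and ATCG00210 (3.31) and the gene AT1G15405 (3.63). The genes that fell most were AT2G39530 (−3.28), TED7 (−2.81), ATCG00810 (−2.70), AT1G06710 (−2.57) and AT5G61350 (−2.19). AT1G15405 lost its call in 10 of 23 alternatives, ATCG00210 in 5 of 21, ATCG00810 in 7 of 22, AT5G61350 in 6, AT1G06710 in 4, AT2G39530 and TED7 in 2 and PBP1 in 1 of 23. With the share of alignments not unique as a covariate AT1G15405 turned to −0.66, ATCG00210 had 0.48 and TED7 −0.60. Genes called higher had a median exonic length of 1099 bases and those called lower 2701, against 1780 over all genes tested. The card1-1 DMBQ libraries had 55.9% of alignments not unique, against 25% in card1-1 mock. The falls over 10 min are therefore not shown to be effects of DMBQ alone.

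Of 11 ERF and DREB factors 7 rose in card1-1, or 8 adjusted over the list alone (median 1.59, camera adjusted p = 8.5e-08), and of 10 zinc finger factors 5, or 6 adjusted over the list alone (median 1.41, 0.00012). Of 16 calcium genes 3 rose, or 5 adjusted over the list alone (median 0.72, 0.00041). Of 15 WRKY factors 3 rose and 1 fell, or 5 and 1 adjusted over the list alone (median 0.65, 0.0265), and of 20 immunity genes 3 rose and 1 fell, or 5 and 2 adjusted over the list alone (median 0.68, 0.0242). Of 23 detoxification genes 2 rose and 1 fell, or 4 and 1 adjusted over the list alone (median 0.57, 0.0265). Of 17 photosynthesis genes 9 rose and 1 fell, or 12 and 1 adjusted over the list alone (median 0.44, camera adjusted p = 6.0e-09), with RBCS1A at 0.71, LHCB1.3 at 0.64 (calls lost in 3 of 23 alternatives each) and RCA, which encodes Rubisco activase, at −0.40. None of these 7 calls held with an estimated correlation (adjusted p = 0.103, 0.123, 0.203, 0.272, 0.272, 0.660 and 0.138). The 10 other measured lists were not called.

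The number of genes called in card1-1 moved widely. With GC and length offsets it was 806, of which 227 were lower. It was 288 (182 higher, 106 lower) when card1-1 was fitted alone, 494 with limma voom, 721 without the 3 libraries above 55% not unique, 119 with that share as a covariate, 616 without card1-1 mock replicate 1 and 758 without card1-1 DMBQ replicate 1.

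In card1-2, ERF5 rose from 12 ± 3.8 to 72.0 ± 11.8 CPM with DMBQ (SD, n = 4; log2 fold change 2.59, SE 0.27, edgeR adjusted p = 3.56e-08) and ZAT10 from 2.28 ± 1.80 to 17.5 ± 2.32 CPM (2.88, SE 0.56, adjusted p = 0.0027). AT3G02840 (3.85), ZAT6 (3.54), AT1G77640 (3.53), CML23 (3.39) and AT1G72920 (3.24) rose most by the naming rule. DRD1, a chromatin remodelling factor of RNA-directed DNA methylation, fell from 12.5 ± 1.46 to 1.60 ± 0.878 CPM (−2.87, adjusted p = 0.00080), and the isocitrate lyase gene ICL fell from 47.0 ± 13.5 to 9.49 ± 4.76 CPM (−2.34, adjusted p = 0.0091). Among the mock groups ICL was high in card1-2 alone, as given below. Its fall here and its higher level without DMBQ therefore rest on the same card1-2 mock libraries and are not separate results. AT5G18750 (−1.73), the pinoresinol reductase gene PRR1 (−1.62) and the phosphatidylinositol 3-kinase gene VPS34 (−1.57) also fell. AT5G18750 lost its call in 14 of 22 alternatives, VPS34 in 7 of 23, AT1G72920 in 7 of 22 and PRR1 in 4 of 23.

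In all, 190 genes rose and 200 fell in card1-2, and with total counts alone for scaling 138 rose and 283 fell. With GC and length offsets the balance turned the other way, and most calls were higher. The median exonic length was 1249.5 bases for the genes called higher and 3114.5 for those called lower. The card1-2 DMBQ libraries had 47.8% of alignments not unique, against 37.3% in card1-2 mock. Of 15 WRKY factors 6 rose, or 8 adjusted over the list alone (median 0.82, camera adjusted p = 4.5e-07). Of 11 ERF and DREB factors 5 rose, or 9 adjusted over the list alone (median 2.11, 1.3e-09). Of 10 zinc finger factors 5 rose, or 6 adjusted over the list alone (median 1.58, 6.4e-07), and of 16 calcium genes 3, or 7 adjusted over the list alone (median 0.85, 2.7e-07). These 4 calls held with an estimated correlation (adjusted p = 0.0197, 0.0197, 0.0223 and 0.0310).

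Of 20 immunity genes 5 rose in card1-2, or 6 with 1 lower adjusted over the list alone (median 0.62, camera adjusted p = 0.0018; adjusted p = 0.129 with an estimated correlation). Jasmonate genes (1 of 17 higher, or 4 adjusted over the list alone; 0.0045), reactive oxygen enzymes (2 of 13 higher by either count; 0.0351) and photosynthesis genes (0 of 17 higher and RCA lower, or 4 and 1 adjusted over the list alone; 9.8e-05) were called up by camera, with estimated-correlation adjusted p = 0.365, 0.167 and 0.289. The 9 other measured lists were not called. The number of genes called in card1-2 was 622 with DESeq2, 195 when card1-2 was fitted alone, 191 with GC and length offsets, and 245, 222, 211 and 248 without card1-2 mock replicates 1, 2, 3 and 4.

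The 180 genes raised in WT responded less in both mutants. Their median log2 fold change was 1.75 in WT, 0.67 in card1-1 and 1.08 in card1-2. In card1-1, 161 of them lay above 0 and 59 were called higher, and 176 had a smaller fold change than in WT (limma's fry on the difference, adjusted p = 0.00039). In card1-2, 172 lay above 0 and 78 were called higher, and 168 had a smaller fold change than in WT (fry adjusted p = 0.0036). By library, the median response was 1.63 to 1.91 in the 4 WT DMBQ libraries, 0.05 to 0.95 in card1-1 and 0.75 to 1.41 in card1-2, without overlap between WT and either mutant. The genes were chosen on these same WT libraries, which favours WT, and the separation by library was not repeated on genes chosen otherwise. Among independent lists of these sizes, 6.38 shared genes would be drawn for card1-1 and 1.93 for card1-2.

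Because genes chosen on WT libraries favour WT, 57 genes were chosen on WT replicates 1 and 2 alone. Their median was 1.94 in WT replicates 3 and 4, 0.87 in card1-1 and 1.35 in card1-2. All 57 were smaller in card1-1 (fry adjusted p = 0.0015) and 55 were smaller in card1-2 (fry adjusted p = 0.0271). For the 180 genes, the median level in card1-1 was 0.38 above WT without DMBQ and −0.64 relative to WT with DMBQ on the log2 scale (fry adjusted p = 0.0584, which does not pass, and 0.00071). In card1-2 the medians were 0.28 and −0.43 (fry adjusted p = 0.119, which does not pass, and 0.0040).

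**Figure D3:**
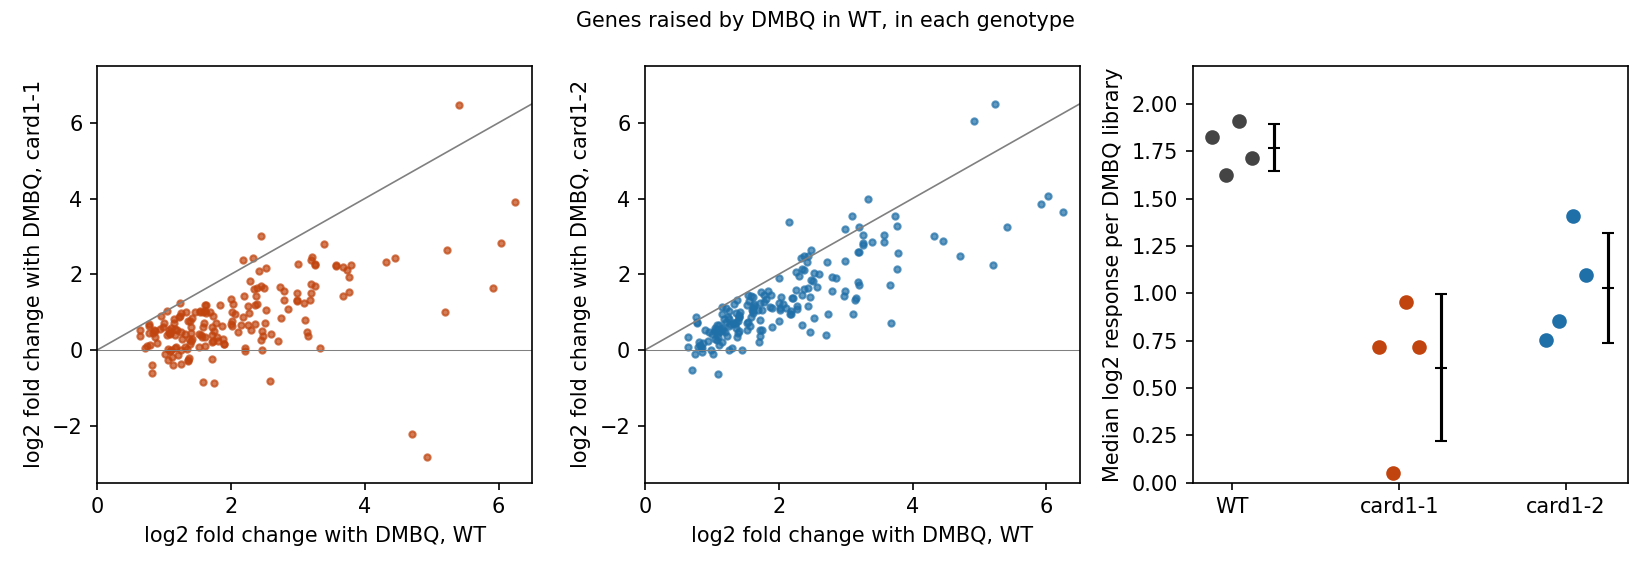
Log2 fold change with DMBQ of the 180 genes raised in WT, in card1-1 (left) and card1-2 (middle) against WT, with the line of equal response, and the median log2 response of these genes in each DMBQ library (right). Right-hand points are libraries and bars are the mean ± SD (n = 4). All 4 WT libraries lie at or above 1.63 and all 8 mutant libraries at or below 1.41, for genes chosen on these WT libraries, which favours WT.

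The difference of response was also tested gene by gene. SOBIR1, a receptor-like kinase that partners immune receptor-like proteins, rose in WT from 38.5 ± 8.60 to 129 ± 23.3 CPM, and in card1-2 it went from 53.1 ± 10 to 77.2 ± 21.9 CPM (log2 fold change 0.53, not past the test). The mean response of both alleles was −1.92 relative to WT (SE 0.26, edgeR adjusted p = 7.12e-05), a call kept in all 39 alternatives. CYP707A3, which encodes an abscisic acid hydroxylase, rose by 3.14 in WT and 1.33 in card1-2 and had 0.49 in card1-1, not past the test (difference −2.23, SE 0.43, adjusted p = 0.0229). WRKY22, a factor of immune signalling, rose by 0.82 in WT, fell by 0.60 in card1-1 and had 0.13 in card1-2, not past the test (difference −1.05). ZAR1 (AT3G50950), an intracellular immune receptor, rose by 0.71 in WT and passed in neither mutant (difference −0.94).

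SCA3, the plastid RNA polymerase, MRL1, a plastid RNA-binding protein, and ACA10, a calcium-transporting ATPase, passed in WT in neither direction and fell in both mutants, with differences of −1.07, −1.09 and −1.03. The plastid gene ATCG00150 (2.06), TUB2 (0.84), TUB3 (0.84) and AT5G60990 (1.00) had larger fold changes in the mutants, and the values of both tubulin genes are uncertain for the reason above. In all, 11 genes differed, 4 with a larger and 7 with a smaller fold change in the mutants, against 123 with DESeq2 (39 larger, 84 smaller) and 93 with limma voom (24 and 69). With the share of alignments not unique as a covariate 6 genes were called, and only 2 of them were among the 11. Apart from SOBIR1, these calls were lost in 5 of 38 (ATCG00150) to 27 of 39 (ZAR1) alternatives. The count fell to 1 without WT mock replicate 2 or WT DMBQ replicate 3 and to 2 without WT mock replicate 1 or 3 or WT DMBQ replicate 2. It was 4, 6, 7, 6, 7, 7 and 6 without WT DMBQ replicates 1 and 4, WT mock replicate 4, card1-2 mock replicates 2 and 3, card1-1 mock replicate 3 and card1-1 DMBQ replicate 4, and 19 without card1-2 DMBQ replicate 2.

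Tested alone, card1-1 differed from WT in 10 genes (1 larger, 9 smaller), among them SOBIR1 (−2.62), WRKY22 (−1.42), MRL1 (−1.34), CYP707A3 (−2.65) and ATCG00150 (2.51). The other 5 lie outside the naming rule and are given after their values were seen: AT1G18740 (−1.64), AT4G20830 (−1.31), CAMBP25 (−1.56), AT1G74450 (−1.34) and AT3G28580 (−2.16). All 5 rose in WT and passed in card1-1 in neither direction. AT3G28580 lost its call in 20 of 31 alternatives, AT1G74450 in 17, CAMBP25 in 6, AT4G20830 in 1 and AT1G18740 in 0. card1-2 differed in 5 genes: ZAR1 (−1.23), ACA10 (−1.28), AT5G60990 (1.24), TUB2 (1.08) and TUB3 (1.06). The split was 3 larger and 2 smaller, and 3 and 4 with total counts alone. No gene was called in both tests. DESeq2 called 99 genes in card1-1 and 58 in card1-2, and limma voom 14 and 17. With the share of alignments not unique as a covariate the counts were 2 and 11, and without the 3 libraries above 55% not unique 31 and 9. The card1-1 count was 39 without card1-1 mock replicate 4 and 32 without card1-1 DMBQ replicate 3, and the card1-2 count was 1 without WT mock replicate 2 or 3, card1-2 mock replicate 2 or 3 or WT DMBQ replicate 4, 2 without card1-2 mock replicate 4, 3 without WT DMBQ replicate 2 or 3, and 10 without card1-2 DMBQ replicate 1.

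In card1-1 tested alone, camera called calcium (−0.74), WRKY (−0.61), ERF and DREB (−1.0), zinc finger (−1.27), immunity (−0.71) and ethylene synthesis (−0.55) genes down and photosynthesis genes up (0.32), with adjusted p from 3.0e-05 to 0.0035, and from 0.0583 to 0.222 with an estimated correlation. In card1-2 it called calcium (−0.48), WRKY (−0.37), ERF and DREB (−0.48), zinc finger (−0.54), immunity (−0.58) and ethylene synthesis (−0.58) genes down and reactive oxygen enzymes up (0.16), with adjusted p from 4.7e-05 to 0.0453, and from 0.0529 to 0.327 with an estimated correlation. Over all genes WRKY22 alone passed in card1-1 and no member in card1-2; adjusted over the list alone the counts were 4, 3, 0, 1, 6, 2 and 0 in card1-1 and 0, 0, 0, 0, 4, 1 and 1 in card1-2, in the order given.

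For both alleles together, pattern-triggered immunity genes had a median difference of −0.70 between both alleles and WT, with 6 of 20 lower adjusted over the list alone (none over all genes; camera adjusted p = 1.1e-06, and adjusted p = 0.0220 with an estimated correlation). Ethylene synthesis genes had a median of −0.70 with 3 of 6 lower adjusted over the list alone (none over all genes; camera adjusted p = 0.00031, and adjusted p = 0.0220 with an estimated correlation). The WRKY (median −0.41), calcium (−0.39), ERF and DREB (−0.73) and zinc finger (−0.89) lists gave camera adjusted p = 0.00031, 0.00090, 0.00090 and 0.0013, and adjusted p = 0.0646, 0.184, 0.184 and 0.184 with an estimated correlation. Among them, WRKY22 alone passed over all genes, and adjusted over the list alone 3, 4, 0 and 1 members were lower. Abscisic acid genes (−0.45, 0.0443) and, with a larger fold change in the mutants, photosynthesis genes (0.23, 0.00058) were called by camera, with no member past either count (adjusted p = 0.325 for both with an estimated correlation). The 9 other measured lists were not called.

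**Figure D4:**
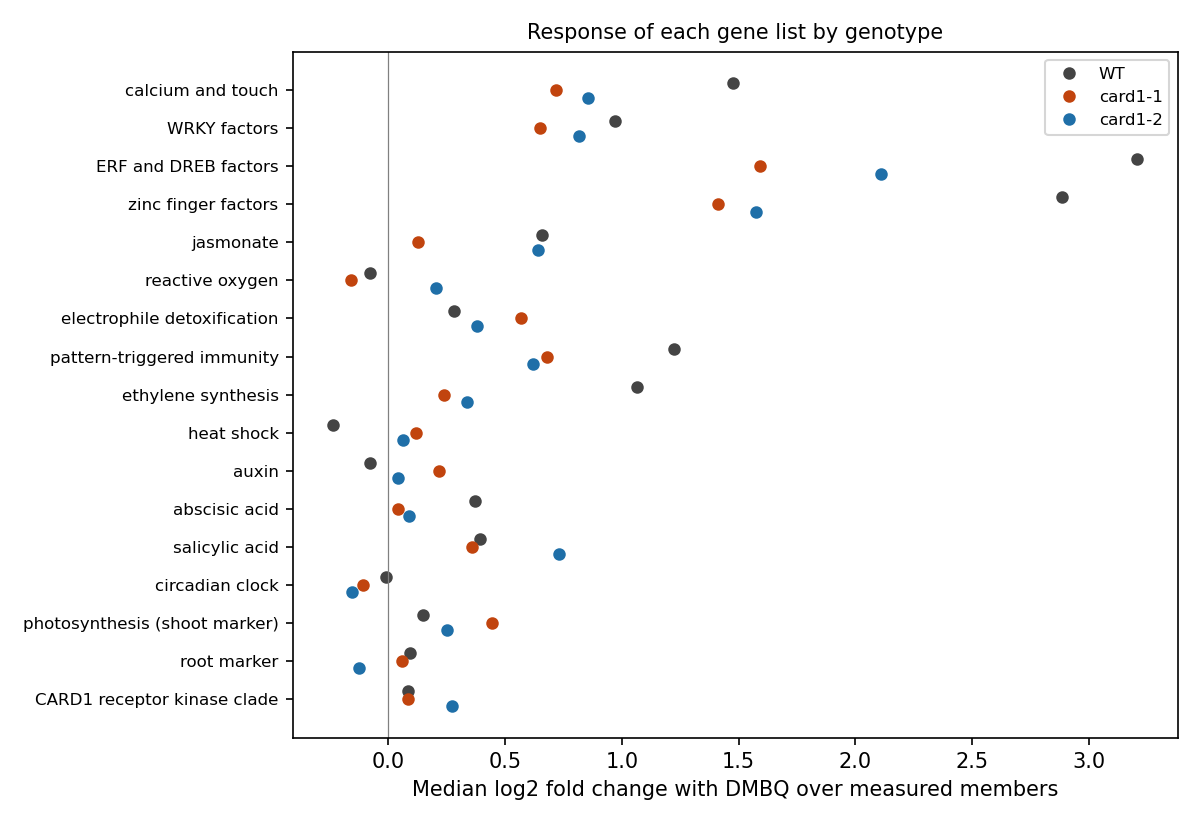
Median log2 fold change with DMBQ over the measured members of each gene list in WT, card1-1 and card1-2; each point is a median over genes, with no error bar. ERF and DREB factors have the highest median in all 3 genotypes, 3.21 in WT, 1.59 in card1-1 and 2.11 in card1-2.

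Without DMBQ, card1-1 did not differ from WT in any single gene by edgeR (0 of 17734 genes, 694 at an unadjusted p under 0.05; 4 with DESeq2 and 0 with limma voom). card1-2 differed in 4 genes (584 at an unadjusted p under 0.05, and 10 called with DESeq2 and 36 with limma voom). Both unadjusted counts were below the number that this threshold gives on average with no difference. The fit pooled the spread over all groups, however. The biological coefficient of variation was 19.3% to 28.0% in the mock groups, and 45.9% and 41.4% in card1-1 and card1-2 DMBQ. A pooled spread can be too wide for the mock groups and make p-values too large, so these counts do not show that the mutants were like WT. ICL, the glyoxylate cycle enzyme of fat-using seedlings, was 47.0 ± 13.5 CPM in card1-2 mock, 2.90 ± 1.69 in WT mock and 6.12 ± 3.14 in card1-1 mock (SD, n = 4; card1-2 against WT 4.08, SE 0.56, edgeR adjusted p = 0.00062), a call kept in all 23 alternatives. AT5G20700 was higher (0.75) and LUL4, a RING-type ubiquitin ligase gene, lower (−1.72). JAL22, a jacalin-lectin gene outside the naming rule and given after its value was seen, was higher (1.1). AT5G20700 lost its call in 10 of 23 alternatives, LUL4 in 8 and JAL22 in 4. The count of 4 became 1 without WT mock replicate 2 or card1-2 mock replicate 3, and 2 without WT mock replicate 3 or card1-2 mock replicate 4, while that for card1-1 became 1 without WT mock replicate 4.

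Detoxification genes were lower as a list in card1-1 mock, with a median of −0.75 over 23 genes (camera adjusted p = 3.0e-12; adjusted p = 0.126 with an estimated correlation). None passed over all genes and 5 passed adjusted over the list alone, and UGT73B4, a glycosyltransferase gene, was at 2.73 ± 0.490 CPM against 13.4 ± 7.28 in WT mock (−2.30, edgeR adjusted p = 0.113). The CARD1 clade (median −0.51, 0.0467), WRKY factors (0.32, 0.0383) and zinc finger factors (0.47, 0.0467) were called by camera too, with 0, 1 and 1 members adjusted over the list alone and estimated-correlation adjusted p = 0.160, 0.352 and 0.412. In card1-2 mock, heat shock genes (−0.58, 0.0014) and detoxification genes (−0.49, 0.0177) were called lower, and ethylene synthesis (0.32, 0.0036) and photosynthesis genes (0.14, 0.0036) higher. In the same comparison the share of alignments not unique was 37.3% against 24.7%, and that of ribosomal RNA genes 0.44% against 0.105% (exact p = 0.0286 for both, the smallest value this design allows; adjusted p = 0.120). Of these lists only ethylene synthesis had a member, 1 of 6, adjusted over the list alone, and the estimated-correlation adjusted p = 0.212, 0.699, 0.152 and 0.699. All other measured lists were not called.

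The 2 mutants shared no gene called in the same direction without DMBQ. Their log2 differences from WT correlated across genes at 0.411, and 0.468 on average (at most 0.491) was reached by simulated unchanged groups that shared a simulated WT mock group. The covariance was 0.0524 against 0.0499 simulated. With the WT mock libraries split in pairs, the correlation lay between −0.05 and 0.09. Genes are not independent replicates, so no p is given.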

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

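The comparison on split WT replicates was planned before the data were examined but what it should show was written only after the result was seen, and chosen only after the result was seen were the tests with the share of alignments not unique as a covariate, those with GC and length offsets, those of the lower calls alone and of card1-2 alone, and those of levels and of the covariate in genes chosen on WT replicates 1 and 2.

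DMBQ responses differed between WT and the mean of both card1 alleles in 11 genes by edgeR's test of the difference. The differences were −1.92 for the immune kinase gene SOBIR1, −2.23 for CYP707A3, −1.05 for WRKY22, −0.94 for ZAR1, −1.03 for ACA10, −1.07 for SCA3 and −1.09 for MRL1. They were 2.06 for the plastid gene ATCG00150, 1.00 for AT5G60990, 0.84 for TUB2 and 0.84 for TUB3. Over the 180 genes raised in WT, the median difference was −1.12 in card1-1 and −0.65 in card1-2.

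The first pattern weighed is the smaller response in both mutants of the genes raised by DMBQ in WT. Selection on the same WT libraries is argued against as the whole cause: 57 genes chosen on WT replicates 1 and 2 had a median of 1.94 in replicates 3 and 4, against 0.87 in card1-1 and 1.35 in card1-2. A higher level before DMBQ is argued against as the whole cause by the same 57 genes, which with DMBQ lay at −0.83 in card1-1 and −0.45 in card1-2 relative to WT replicates 3 and 4 (fry adjusted p = 0.000657 and 0.0166), while the −0.64 of the 180 genes in card1-1 decides nothing because they were chosen on the treated WT libraries. With the share of alignments not unique as a covariate, the median difference of the 57 genes was −1.46 in card1-1 and −0.70 in card1-2 (fry adjusted p = 0.00105 and 0.0205), against −1.16 and −0.60 without it. A linear trend with that share, as estimated within groups, is thus argued against as the whole cause in card1-2, though the shares overlap there through 1 library alone. The share was 33.6% to 41.2% in card1-2 mock. With DMBQ it was 31.9% in replicate 2 and 47.4% to 61.1% in the other card1-2 libraries. The covariate was not fitted without that replicate. In card1-1 the share did not overlap between mock (17.3% to 32.3%) and DMBQ (48.3% to 66.5%). The covariate cannot decide there, and such a trend stays open. Other sides of library quality go with genotype and stay open (over the 8 mutant DMBQ libraries the median response and that share had a Spearman rho of −0.048, exact p = 0.935, and a Pearson r of 0.141, exact p = 0.744, or 0.501 without card1-2 DMBQ replicate 2 and card1-1 DMBQ replicate 4), as does a need for CARD1 in part of the early response, a candidate explanation that the genotype names.

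The second pattern weighed is that more genes were called with DMBQ in card1-1 (1189) and card1-2 (390) than in WT (182), many of them lower. A pooled spread too small for the noisier mutant libraries may account for the order, since fits on each genotype alone called 288 in card1-1, 195 in card1-2 and 349 in WT. The median fold change of the called genes went from 0.87 to 0.86 in both mutants, with SE from 0.216 to 0.237 and from 0.198 to 0.205. Whether the wider SE or the fewer libraries in these fits ended the calls was not tested. The pooled spread is not shown to account for the numbers: with each group's own spread, simulated unchanged responses gave 7 calls in card1-1 and 0 in card1-2. That simulation was run once and drew each gene independently. It holds no noise shared across genes and does not weigh against such noise. A GC or length trend is argued against as the whole cause in card1-1, where 806 genes were called with offsets for both (630 of them among the 1189). It stays open in card1-2, where 191 were called against 187 in WT (149 of the 191 among the 390, median fold change 0.87 to 0.68, SE 0.198 to 0.196). It also stays open for part of the lower calls, which went from 560 to 227 in card1-1 and from 200 to 43 in card1-2. Their median fall went from 0.88 to 0.62 (SE 0.217 to 0.215) and from 0.81 to 0.58 (SE 0.188 to 0.184). Whether the smaller fall alone ended these calls was not tested. A trend with the share of alignments not unique is argued against as the whole cause in card1-2. There 361 genes were called with the share as a covariate (270 of them among the 390, median fold change 0.87 and 0.88, SE 0.198 and 0.218). As given above, the shares of card1-2 mock and DMBQ overlap through 1 library alone, which limits this result. In card1-1 119 genes were called, and the trend cannot be told apart from the treatment. The median fold change there went from 0.87 to 0.83 while its SE rose from 0.216 to 0.371. A biological difference between genotypes stays open and untested.

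Other splits of the same libraries were counted for each number of genes. Of 35 splits each, only the real one called as many genes for the response in WT (182, highest other 0), card1-1 (1189, highest other 50) and card1-2 (390, highest other 1), and for card1-2 against WT without DMBQ (4, highest other 0). Chance alone is thus unlikely but not excluded, since 1 of 35 is the smallest share possible and the shares are unadjusted. The splits do not tell treatment or genotype from library quality, which differed between the same groups. For card1-1 against WT without DMBQ, edgeR called 0 genes (highest other 2), so 35 of 35 splits call as many by construction and decide nothing. In that comparison 694 genes had an unadjusted p under 0.05, fewer than this threshold gives on average with no difference. With the spread pooled over noisier groups, this count does not show that card1-1 and WT were alike. DESeq2 called 4 and limma voom 0. For the difference of response, genotypes were exchanged within treatment. As many genes were called by 4 of 100 splits in card1-1 (10, highest other 23) and 1 of 100 in card1-2 (5, highest other 4). For both alleles 3 of 100 did so (11, highest other 537). These shares do not exclude chance: they are unadjusted, and other splits called more genes in card1-1 and in both alleles. The mutant DMBQ libraries also had a wider spread than those of WT, so the exchanged libraries were not alike. What sets the split with 537 genes apart was not tested.

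The share of alignments not unique, which lies outside the gene counts, had a mean of 33.4% in WT DMBQ and 55.9% in card1-1 DMBQ, against 24.7% and 25% in their mock groups. Single libraries lay far from the other 3 of their group in 15 of 187 sets of 4 values examined, by a criterion that sets a library apart in about 1 in 20 groups by chance. WT DMBQ replicate 3 had 2453832 gene counts (others 3471047 to 3567209). WT DMBQ replicate 2 had 41.8% of alignments not unique (others 29.7% to 31.5%) and 0.21% of counts in mitochondrial genes (others 0.0772% to 0.0855%). card1-1 mock replicate 3 had 0.242% of counts in ribosomal RNA genes (others 0.0455% to 0.078%). card1-1 mock replicate 1 had 9.46% of counts in its 10 most abundant genes (others 5.44% to 5.81%). Its correlation with the mean of the other libraries of its group was 0.937 (others 0.962 to 0.965).

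Single-gene values apart from their group, in CPM, were AT4G29780 in WT mock replicate 2 (14.2, others 7.81 to 8.50), WRKY40 in WT mock replicate 1 (1.20, others 5.68 to 7.24) and ERF5 in WT DMBQ replicate 3 (126, others 85.2 to 89.1). WT mock replicate 4 was low in TUB3 (252, others 342 to 351) and TUB2 (388, others 495 to 501), and card1-1 mock replicate 1 was high in TUB3 (329, others 263 to 271). ZAR1 was high in card1-2 mock replicate 3 (131, others 90.8 to 96.6), AT1G18740 low in card1-1 DMBQ replicate 2 (24.2, others 63.3 to 75.4) and ICL low in WT mock replicate 3 (0.426, others 3.23 to 4.09).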

How the results depend on the processing

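Chosen after seeing the data were the runs without the 3 libraries above 55% not unique, with that share as a covariate, at equal depth, without organelle and ribosomal RNA genes and with GC and length offsets, and those leaving out mutant libraries for the genes raised in WT. For single named genes, 5480 alternatives stayed on the same side of the threshold, 324 were weaker and 52 stronger. A turn of direction was not counted where a gene passed in neither fit, and many of the 5480 are genes that passed in neither. Of 201 named results, each a gene in a comparison, 81 were called in the reported analysis, and 43 of these lost no call. For gene lists 150 alternatives were the same and 74 weaker, 42 of them with an estimated correlation and 31 with fry. AT1G15405 turned direction in card1-1 with the covariate (−0.66, adjusted p = 0.843, the highest of its alternatives; 3.63 in the reported analysis). Replicate numbers were not taken as pairs: over 20 pairs of libraries the correlation lay between −0.018 and 0.235 and was over 0.1 in 7. In 11 of the 20 comparisons a library correlated best with its own number among 4 candidates, a hint from the data and not from the design. A batch shared by number is thus not excluded, and counts with the replicate block are given below. DESeq2 gave no adjusted p for 12035 genes in card1-1 against WT without DMBQ. The same held for 8940, 11691 and 11003 genes in the differences of card1-1, card1-2 and both alleles, and for 5159 in the card1-2 response. Depth was not shown to limit the differences of both alleles, which were 11 at equal depth too, 9 of them among the reported 11. Thinning cannot show whether more depth would add calls, and the 15% of 2-fold differences recovered in simulation do not tell depth from spread. The cause was not tested for any of the values that follow, apart from the stricter thresholds and the fewer libraries.

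The response in WT (182) became 372 with limma voom, 349 on its own groups and 119 at an adjusted p under 0.01. That in card1-1 (1189) became 494, 288 and 419 in the same order, 411 with a log2 fold change of at least 1, 721 without the 3 libraries and 119 with the covariate. That in card1-2 (390) became 622 with DESeq2, 195 on its own groups, 140 with a log2 fold change of at least 1, 163 at an adjusted p under 0.01 and 191 with GC and length offsets. The difference in card1-1 (10) became 16 with no filter, 99 with DESeq2, 58 with a replicate block, 6 at an adjusted p under 0.01, 31 without the 3 libraries and 2 with the covariate. That in card1-2 (5) became 58 with DESeq2, 17 with limma voom, 12 on its own groups, 12 with the block, 1 at an adjusted p under 0.01, 9 without the 3 libraries and 11 with the covariate. That in both alleles (11) became 19 with total counts, 123 with DESeq2, 93 with limma voom, 32 with the block, 1 at an adjusted p under 0.01, 17 without the 3 libraries and 6 with the covariate. Without DMBQ, card1-1 (0) became 1 with no filter, 4 with DESeq2, 6 with the block and 3 without the 3 libraries. card1-2 (4) became 7 with no filter, 10 with DESeq2, 36 with limma voom, 19 on its own groups, 12 with the block, 1 at an adjusted p under 0.01 and 2 with the covariate; the alleles shared 1 gene with the block and 0 in the reported analysis, with RLE size factors and in 3 splits of the WT mock libraries, the other settings in which this was counted. The WT median of the genes raised in WT (1.75) became 1.95 with a log2 fold change of at least 1 and 1.94 for genes called on WT replicates 1 and 2.

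With each library left out in turn, the responses ranged from 117 to 167 in WT, 616 to 1178 in card1-1 and 211 to 553 in card1-2, and the differences from 7 to 39 in card1-1, 1 to 10 in card1-2 and 1 to 19 in both alleles. Without DMBQ the counts ranged from 0 to 1 in card1-1 and 1 to 4 in card1-2. The medians of the genes raised in WT ranged from 1.72 to 2.00 in WT (2.00 without WT mock replicate 1), 0.57 to 0.80 in card1-1 and 0.94 to 1.16 in card1-2.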

Other observations

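In this part the count without genes called in WT was chosen only after the result was seen. card1-1 and card1-2 shared 87 genes called higher (6.74 drawn for independent lists of these sizes) and 97 called lower (6.32 drawn). Without the genes called in the same direction in WT, they shared 45 called higher (3.64 drawn) and 97 called lower (6.31 drawn). MRL1, the plastid RNA-binding protein, fell from 226 to 71.8 CPM in card1-1 and from 194 to 87.4 CPM in card1-2. SCA3, the plastid RNA polymerase, fell by 0.94 and 1.22 on the log2 scale, and ACA10 by 0.58 and 1.07. Both mutants' DMBQ libraries had more alignments that were not unique (55.9% and 47.8%, against 33.4% in WT DMBQ), and genes called lower had a median exonic length of 2701 bases in card1-1 and 3114.5 in card1-2 (1780 over all genes).

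Counts in ribosomal RNA genes went from 0.105% in mock to 0.238% with DMBQ in WT, from 0.109% to 1.05% in card1-1 and from 0.44% to 0.797% in card1-2 (exact p = 0.0286, 0.0571 and 0.4). Counts in mitochondrial genes went from 0.0899% to 0.114% in WT, from 0.0938% to 0.484% in card1-1 and from 0.145% to 0.358% in card1-2 (exact p = 0.686, 0.0286 and 0.229). None of these 6 passed after adjustment over 42 tests (adjusted p from 0.120 to 0.778). With a smallest possible p of 0.0286 the adjusted tests could hardly pass, so this does not show that the shares were alike.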
